A study of Mus musculus with 36 samples.

How the data were processed

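RNA-seq was from bone marrow-derived macrophages (BMDMs) of wild-type (WT) and N4bp1 knockout (KO) mice on the C57BL/6N background, grown in M-CSF. Macrophages received R837 (imiquimod, a TLR7 agonist) for 3 h or 7 h, or for 3 h followed by actinomycin D (ActD, which blocks transcription) for 0.5, 1, 2 or 4 h. Each of the 12 groups (2 genotypes by 6 conditions) held 3 libraries, 36 in all. Per the labels the 3 were macrophages of 3 individual mice. The p-values of KO against WT within a condition therefore measured variation between mice, pooled over all 12 groups. The labels carry no replicate numbers, so replicates were numbered in the order of the records and libraries could not be tied across conditions. Libraries of different conditions within a genotype may come from the same mice, which the model did not use. Comparisons over time therefore treated all libraries as independent. The pooled variation used for KO against WT did so too, and its p-values may be too small if mice were shared. In the straight-line fits described below, the residual also held the misfit of the line. No unstimulated macrophages were analysed here, so every comparison was among R837-treated groups.

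Per the submitters' processing notes, reads were aligned with GSNAP to GRCm38. The program that counted reads over genes, the annotation release and the strand setting were not given in the sources used here. The deposited values were a count and an RPKM per gene and library, with the gene width; the counts were whole numbers and were used for all tests, and the RPKM values of the authors were used only to check the counts. Gene counts summed to 90.86 to 91.76% of the total implied by the deposited RPKM values. The 52636 gene identifiers were named from GENCODE M21, in which 52489 were found; the other 147 held at most 0.002% of the counts of a library. Counts per library totalled 20.3 to 46.1 M (median 26.3 M), 0.034 to 0.077% of them on mitochondrial genes. The 10 genes with most counts held 10.0 to 15.5% of a library, and the highest was Ctsb in most libraries (2.03 to 2.99%), Saa3 in the 3 libraries of KO at 7 h and Lyz2 in 1 library of WT after 4 h of ActD.

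Some genes with near-identical copies in the genome were almost uncounted: the median count per library was 1.5 for Gapdh, 1 for Rps6, 8 for Ppia, 13 for Actg1, 22.5 for Hmgb1 and 27.5 for Rpl3, whereas it was 24085 for Eef1a1, 64096.5 for Actb and 269239.5 for Fth1. Of these 9 genes only Gapdh and Rps6 did not pass the filter. Low counts of such genes were therefore not read as low expression. The list of ribosomal proteins and elongation factors, which also served as the stable reference, held only 0.64 to 1.08% of the counts.

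Counts were normalized by TMM, genes were kept by filterByExpr (13748 tested, 13537 in the slope model), and tests were edgeR quasi-likelihood F tests (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 7.5%. One model of the 12 groups on all 36 libraries gave 12 contrasts: KO minus WT in each of the 6 conditions, 7 h minus 3 h of R837 in each genotype, 7 h of R837 minus 3 h of R837 with 4 h of ActD in each genotype, and the genotype difference (interaction) of the last 2 kinds. A second model fitted log2 expression against hours of ActD (0, 0.5, 1, 2 and 4) in each genotype on 30 libraries. Its slopes were relative to the average transcript, because no spike-in was used here and total RNA can fall under ActD. CPM values are TMM-normalized means ± SD of 3 libraries, and log2 fold changes and slopes are given ± SE.

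Genes were named by a rule set before the data were examined. It took N4bp1, 9 fixed cytokines (Tnf, Il6, Il12b, Il1b, Il10, Cxcl1, Cxcl2, Csf3, Ccl5), the largest changes that passed, and the members with the smallest p of each list. Genes ranked by change had a mean CPM of at least 5, or 20 for slopes within a genotype. In contrasts of 2 groups, the libraries of the 2 groups also had to be fully apart. Changes called largest, highest or lowest in the results are those among genes ranked in this way. Predicted genes and clones were not named by rank, and results of a few single genes are not reported here. Also set before the data were examined were the contrasts, the lists and the alternatives RLE and ribosomal stable-reference normalization, DESeq2 (1.42.0), no filter, a stricter filter (CPM of 1 in 3 libraries), adjusted p below 0.01, a fit of only the libraries compared, leaving out each library, fry, an estimated inter-gene correlation, slopes over 0 to 2 h and a 4 h minus 0 h contrast. Removal of the trend with gene length, the contrasts at single ActD times and the removal of 2 libraries together were added after results were seen.

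Gene lists were written from general knowledge before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 25 lists tested. The 26 lists were cytokines and chemokines (31 members tested), NF-kB pathway and feedback (24), IKK family and caspase-8 complex (24), type I interferon response (33), immediate early genes (25), mRNA decay factors (32), AU-rich element transcripts (22), Regnase-1 target transcripts (14), Toll-like receptor pathway (29), inflammasome and cell death (24), macrophage effector genes (24), cholesterol synthesis (20), glycolysis and hypoxia (20), proliferation (22), p53 targets (17), ribosomal proteins and elongation factors (44), mitochondrially encoded (10), and markers of macrophages (16), neutrophils (15), dendritic cells (12), T and NK cells (7, or 5 in the slope model), B cells (8), erythroid cells (1 of 13), mast cells and basophils (7), fibroblasts and stroma (11) and osteoclasts (8). The erythroid list could not be tested as a list, and lists shared members, such as Tnf, Il6 and Cxcl1.

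The testing was checked on simulated data built from these counts, with 200 of 13748 genes changed. The changed genes were drawn from those with a mean CPM of at least 5, so detection at lower counts was not simulated. In KO against WT at 3 h, changes of 1.2, 1.5, 2 and 4-fold were found in 30, 98, 100 and 100% of 50 genes each, and 12 of 13548 unchanged genes were called. For the genotype difference in slope, changes of 0.1, 0.2, 0.35 and 0.5 log2 per h were found in 24, 72, 96 and 98%, with 3 unchanged genes called. A raised list was called and 0 of 25 unchanged lists were called by camera. Simulated genes varied independently and held no trend with gene length between genotypes, unlike the data. The share of false calls in the data may therefore be higher.

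No replicate pair within a group was a copy, since the chi-square per degree of freedom of such pairs was at least 2.23. Pairs across groups were not compared. Replicate 3 of WT after 0.5 h of ActD and replicate 3 of WT after 4 h of ActD stood apart from the other replicates of their groups (up to 45.63 and 28.72), and both were kept.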

Results

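At 3 h of R837, KO macrophages held more transcript of several inflammatory cytokines than WT macrophages (n = 3 libraries per group). Tnf, encoding a cytokine released early after Toll-like receptor engagement, was at 1729 ± 25.4 CPM in KO and 895.7 ± 10.2 CPM in WT (1.93-fold, log2 fold change 0.95 ± 0.06, edgeR quasi-likelihood adjusted p = 4.81e-16). Il6, encoding interleukin 6, was at 96.92 ± 15.4 against 37.12 ± 4.65 CPM (2.6-fold, log2 1.38 ± 0.11). Cxcl1, encoding a neutrophil chemoattractant, was at 722.6 ± 92.5 against 295.1 ± 32.9 CPM (log2 1.29 ± 0.10). Cxcl2 (log2 0.70 ± 0.09), Csf3 (0.56 ± 0.16), Ccl5 (0.42 ± 0.13) and Il1b (0.31 ± 0.08) were also higher in KO. Il10, which encodes an anti-inflammatory cytokine, was lower (-0.25 ± 0.09, edgeR adjusted p = 0.0465). This call lay near the threshold, and stable-reference scaling shifted the contrast upward by a median of 0.199 log2. Il12b did not pass the threshold (0.33 ± 0.14, edgeR adjusted p = 0.0662). The targeted gene itself was N4bp1 (ENSMUSG00000031652, chromosome 8, 86808160 to 86885258, minus strand). It was at 84.09 ± 2.45 CPM in KO and 133.5 ± 12 CPM in WT (log2 -0.67 ± 0.08, edgeR adjusted p = 1.08e-08), reduced and not absent. Reads can come from exons outside a deletion, and the deletion was not given in the sources used here.

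Among the genes ranked, the largest differences at 3 h were in other genes. Igha, encoding the immunoglobulin alpha constant region (chromosome 12, 113254830 to 113260236), was at 27.58 ± 2.41 CPM in KO and 4.142 ± 0.484 CPM in WT (6.67-fold, log2 2.74 ± 0.13). Next came the interferon-inducible surface protein gene Ly6i (log2 2.23 ± 0.14) and the neutrophil granule protease gene Ctsg (2.11 ± 0.60, with an SD of 11.4 around a KO mean of 10.67 CPM). The Ras activator gene Rasgrp1 (1.95 ± 0.13) and the immunoglobulin joining chain gene Jchain (1.91 ± 0.14) followed. The adenosine receptor gene Adora2a was at 67.22 ± 3.3 against 18.42 ± 1.15 CPM (1.87 ± 0.10). In the other direction, Id1, encoding an inhibitor of helix-loop-helix transcription factors, was lowest in KO relative to WT (9.634 against 27.13 CPM, log2 -1.50 ± 0.11). It was followed by the neuronal pentraxin gene Nptx1 (-1.35) and the mitotic kinase gene Pbk (-1.27). In all, 3818 of 13748 genes differed. Of these 2087 were higher and 1731 lower in KO, with 202 and 77 at least 2-fold. Without replicate 1 of KO 2202 genes were called, and without replicate 3 of WT 2375. Ribosomal stable-reference scaling moved this split to 3782 higher and 428 lower through a median shift of 0.20 log2. The difference rose with gene length (Spearman correlation 0.3). After removal of that trend 74.5% of the calls remained (2845 of 3818), as did 263 of the 279 that were at least 2-fold.

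Among the gene lists at 3 h, transcripts targeted by the endonuclease Regnase-1 were shifted up in KO, with 12 of 14 members higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 3.82e-15). NF-kB pathway and feedback genes were higher in 20 of 24 and lower in 0 (21 and 1 adjusted over the list alone; camera adjusted p = 4.72e-15). Among them were Traf1 (log2 0.89), which encodes a TNF receptor adaptor, Tnfaip3 (0.61), which encodes the ubiquitin-editing enzyme A20, and Nfkbie (0.60), which encodes an inhibitor of NF-kB. Cytokines and chemokines were higher in 16 of 31 and lower in 5 (19 and 5 adjusted over the list alone; camera adjusted p = 5.9e-14). AU-rich element transcripts were higher in 12 of 22 and lower in 2 (13 and 2 adjusted over the list alone; 3.17e-12). Macrophage effector genes were higher in 17 of 24 and lower in 2 (17 and 2 adjusted over the list alone; 1.18e-12), with the matrix protease genes Mmp9 at 1.195 and Mmp14 at 1.03. Immediate early genes were higher in 12 of 25 and lower in 3 (14 and 3 adjusted over the list alone; 0.000127). In that list Maff, encoding a small Maf factor, was at 0.94 and Atf3, encoding a stress-induced factor, at -0.78.

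Proliferation genes were lower in KO at 3 h in 18 of 22 members and higher in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1.18e-12). The cell-cycle kinase gene Cdk1 was at -1.01, the ribonucleotide reductase gene Rrm2 at -0.90 and the survivin gene Birc5 at -0.89. Cholesterol synthesis genes were lower in 15 of 20 and higher in 0 (16 and 1 adjusted over the list alone; 1.86e-09), with the sterol oxidase gene Msmo1 at -0.57. Fibroblast and stromal markers were higher in 7 of 11 and lower in 0 (7 and 0 adjusted over the list alone; 9.04e-05), among them the collagen genes Col1a1 (1.14) and Col1a2 (1.06). Osteoclast markers were higher in 4 of 8 and lower in 1 (4 and 1 adjusted over the list alone; 0.00792), with the fusion protein gene Ocstamp at 1.69. With an estimated correlation in place of the preset one, the 10 lists named so far still passed (0.0273 for the immediate early and the fibroblast list).

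Further lists passed camera at 3 h only with the preset correlation. The first was the IKK family and caspase-8 complex (9 of 24 higher and 2 lower, also 9 and 2 adjusted over the list alone; camera adjusted p = 0.0357, adjusted p = 0.0954 with an estimated correlation). Also in this class were mRNA decay factors (15 of 32 higher and 2 lower, 17 and 2 adjusted over the list alone; 0.00395, adjusted p = 0.328 with an estimated correlation) and the Toll-like receptor pathway (12 of 29 higher and 2 lower, 12 and 3 adjusted over the list alone; 0.0479, adjusted p = 0.473 with an estimated correlation). So were dendritic cell markers (5 of 12 higher and 2 lower, the same adjusted over the list alone; 0.0464, adjusted p = 0.218 with an estimated correlation) and ribosomal proteins and elongation factors (1 of 44 higher and 11 lower, the same adjusted over the list alone; 7e-04, adjusted p = 0.365 with an estimated correlation). In the IKK list, the ubiquitin ligase gene Birc2 was at 0.47 and Cflar, encoding the caspase-8 regulator FLIP, at 0.40. Removal of the length trend ended the calls of the IKK (0.07), decay factor (0.117), Toll-like receptor (0.0724) and ribosomal (0.106) lists.

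The remaining lists did not pass camera at 3 h. Among pathways these were type I interferon response (7 of 33 higher and 8 lower; adjusted p = 0.933), inflammasome and cell death (5 and 5 of 24; 0.856), glycolysis and hypoxia (6 and 5 of 20; 0.975), p53 targets (4 and 1 of 17; 0.997) and mitochondrially encoded genes (1 and 0 of 10; 0.673). Among markers they were those of macrophages (5 and 4 of 16; 0.878), neutrophils (5 and 0 of 15; 0.237), T and NK cells (1 and 1 of 7; 0.0681), B cells (2 and 1 of 8; 0.673) and mast cells and basophils (1 and 1 of 7; 0.933). Adjusted over the list alone these were in turn 7 and 8, 5 and 6, 6 and 6, 4 and 1, 0 and 0, 6 and 4, 5 and 0, 1 and 1, 2 and 1, and 1 and 1. The p53 list was tested as up with a median of -0.09 and a mean of -0.01. Macrophage markers were tested as up with a median of 0.02 and a mean of -0.02. Interferon-induced genes went both ways. Irf7, encoding an interferon regulatory factor, was at 0.61 and Cxcl10, encoding a T cell chemoattractant, at -0.62. Epor, the only erythroid marker tested, did not pass (-0.19, edgeR adjusted p = 0.811).

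By 7 h of R837, the KO excess of cytokine transcripts was larger (n = 3 libraries per group). Il6 was at 364.6 ± 5.14 CPM in KO and 28.21 ± 0.98 CPM in WT (12.9-fold, log2 3.69 ± 0.12), and Cxcl1 at 1070 ± 20.2 against 161 ± 8.67 CPM (6.64-fold). Csf3, encoding the granulocyte growth factor G-CSF, was at 338.8 ± 19.5 against 61.26 ± 3.86 CPM (5.53-fold) and Cxcl2 at 1629 ± 12.1 against 323.5 ± 11.6 CPM (5.03-fold). Il1b, encoding interleukin 1 beta, was at 8809 ± 121 against 2209 ± 37.2 CPM (3.99-fold) and Il12b at 820.4 ± 30.2 against 215.9 ± 15.2 CPM (3.8-fold). Il10 was at 245.4 ± 13.7 against 93.34 ± 3.83 CPM (2.63-fold), Tnf at 1356 ± 36.2 against 572.5 ± 19.1 CPM (2.37-fold) and Ccl5 at 1761 ± 37.9 against 908.8 ± 25.3 CPM (1.94-fold). N4bp1 remained lower in KO, at 143.3 ± 1.99 against 174.5 ± 6.91 CPM (log2 -0.29 ± 0.08, edgeR adjusted p = 0.00275).

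Highest by fold at 7 h among the genes ranked was Ptx3, encoding a secreted pentraxin (15.83 ± 0.894 against 0.9124 ± 0.224 CPM, 17.3-fold, log2 4.11 ± 0.19). After it came the TNF family gene Tnfsf15 (13.5-fold), Il6 and the interleukin 1 alpha gene Il1a (718.6 against 86.62 CPM, 8.3-fold). Cxcl3 (8.25-fold), the activin gene Inhba (8.16-fold), the mTORC1 inhibitor gene Ddit4 (8.1-fold) and the receptor gene Trem1 (7.68-fold) followed. The enzyme gene Ptgs2, which encodes cyclooxygenase 2, was at 4691 ± 166 against 927.7 ± 34.1 CPM (5.06-fold). Lower in KO were the Rab3A-interacting factor gene Rab3il1 (15.06 against 97.03 CPM, log2 -2.69) and the sestrin gene Sesn1 (-2.57), then the sorting nexin gene Snx24 (-2.42), the thrombomodulin gene Thbd (-2.37) and the endocytic adaptor gene Hip1 (-2.36). In total 4201 genes differed, 2126 higher and 2075 lower in KO. Of these 412 and 298 were at least 2-fold. Of the genes called at 3 h, 1006 higher (323 expected if independent) and 771 lower (261 expected) were called in the same direction at 7 h. Both times may hold macrophages of the same mice, so the calls may not be independent. In the opposite one 90 and 48 were called. Of the 710 calls that were at least 2-fold, 701 remained after removal of the length trend, whose correlation was 0.1 at this time.

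Among the lists at 7 h, Regnase-1 targets were higher in KO in 13 of 14 members and lower in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 9.23e-59). Cytokines and chemokines were higher in 23 of 31 and lower in 2 (25 and 3 adjusted over the list alone; 3.1e-52). AU-rich element transcripts were higher in 18 of 22 and lower in 2 (19 and 2 adjusted over the list alone; 1.44e-51). Macrophage effector genes were higher in 21 of 24 and lower in 2 (21 and 2 adjusted over the list alone; 1.06e-34). NF-kB pathway and feedback genes were higher in 22 of 24 and lower in 0 (23 and 0 adjusted over the list alone; 5.02e-31), with Nfkbie at 1.41 and Traf1 and Tnfaip3 at 1.37 each. Immediate early genes were higher in 16 of 25 and lower in 4 (the same adjusted over the list alone; 2.34e-11), with the nuclear receptor gene Nr4a1 at 6.17-fold. Cholesterol synthesis genes were lower in 17 of 20 and higher in 0 (the same adjusted over the list alone; 3.56e-09), with the squalene epoxidase gene Sqle at -0.86. Macrophage markers were lower in 7 of 16 and higher in 2 (the same adjusted over the list alone; 0.00223), with the Fc receptor gene Fcgr1 at -0.98. Dendritic cell markers were higher in 7 of 12 and lower in 1 (7 and 2 adjusted over the list alone; 0.000289), with the class II gene H2-Ab1 at 1.03.

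Other lists passed at 7 h only with the preset correlation. These were the IKK family and caspase-8 complex (9 of 24 higher and 0 lower, 10 and 0 adjusted over the list alone; camera adjusted p = 0.0364, adjusted p = 0.0983 with an estimated correlation) and glycolysis and hypoxia (9 of 20 higher and 2 lower, 9 and 3 adjusted over the list alone; 0.000958, adjusted p = 0.165 with an estimated correlation). They also included proliferation (1 of 22 higher and 14 lower, 1 and 15 adjusted over the list alone; 0.00437, adjusted p = 0.266 with an estimated correlation) and fibroblast and stromal markers (8 of 11 higher and 0 lower, 9 and 0 adjusted over the list alone; 0.000958, adjusted p = 0.061 with an estimated correlation). Ikbkb, which encodes the kinase IKK beta, was at 0.45. The proliferation marker gene Mki67 was higher at 1.38, while the kinase gene Bub1 was at -0.79. The IKK call ended without the length trend (0.0808). Among lists that did not pass were type I interferon response (6 higher and 8 lower; camera adjusted p = 0.662), mRNA decay factors (12 and 4; 0.068), the Toll-like receptor pathway (5 and 9; 0.573) and inflammasome and cell death (5 and 8; 0.672). The Toll-like receptor pathway was tested as down with a median of 0.05 and a mean of -0.11. Adjusted over the list alone the 4 were at 6 and 9, 16 and 4, 7 and 10, and 6 and 9. In these lists the interferon regulatory factor gene Irf5 (-1.52) and the receptor gene Tlr13 (-1.24) were lower in KO and the inflammasome sensor gene Nlrp3 (1.37) was higher.

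**Figure D1:**
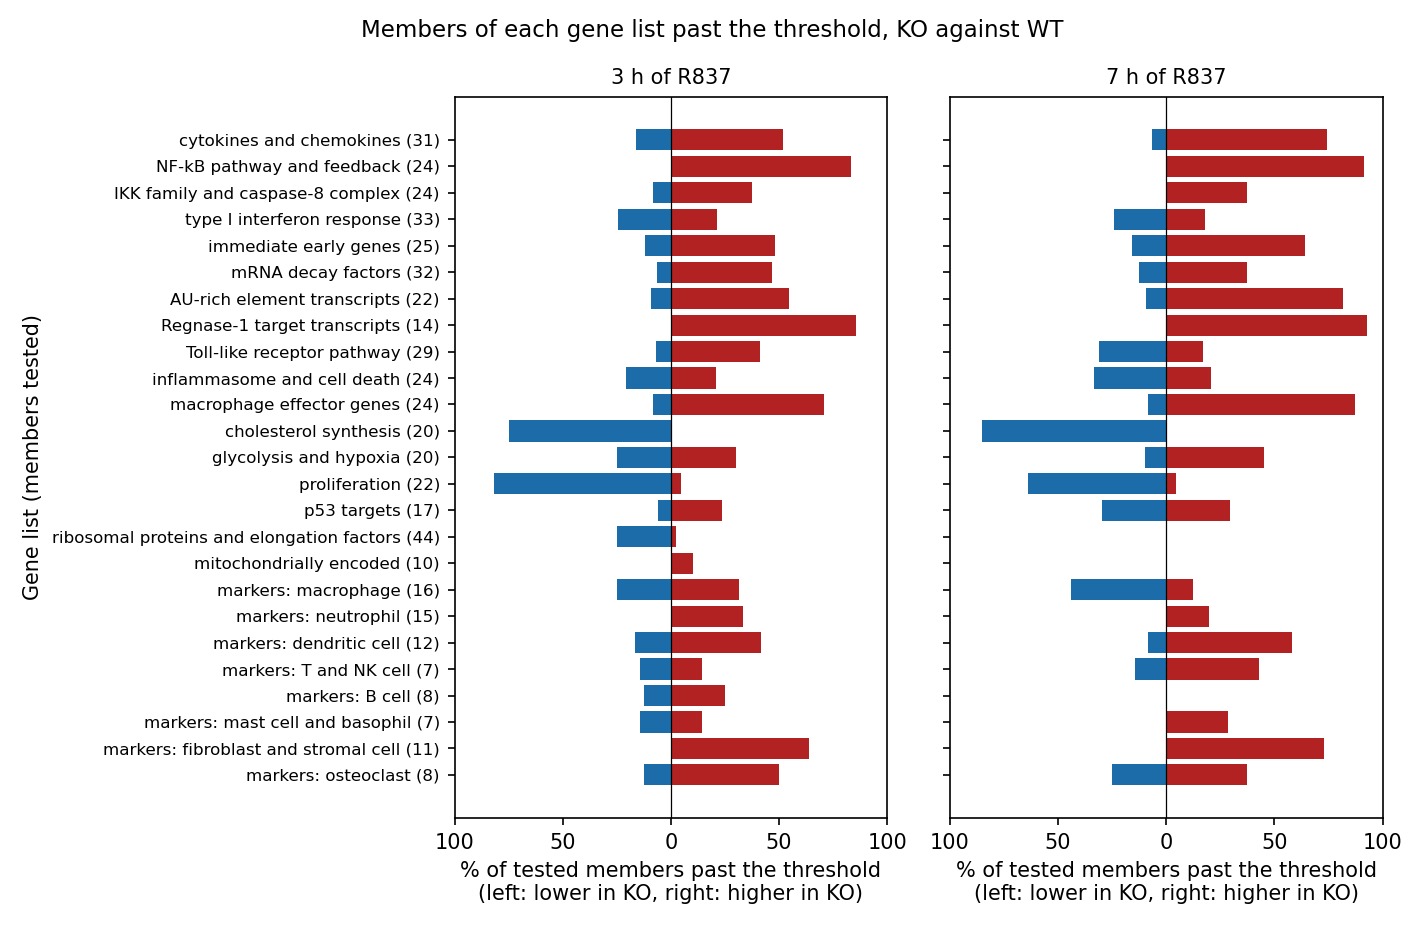
Percentage of the tested members of each gene list (bars, horizontal axis) called higher or lower in KO than in WT at 3 h and at 7 h of R837, with n = 3 libraries per group. Regnase-1 targets had 12 of 14 members higher at 3 h and 13 at 7 h, and cholesterol synthesis had 15 and 17 of 20 lower.

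Between 3 h and 7 h of R837, WT macrophages lowered many early transcripts and raised others (n = 3 libraries per time). Il10 fell by 1.64 ± 0.10 log2 (93.34 against 291.5 CPM), Cxcl1 by 0.87, Tnf by 0.65, Cxcl2 by 0.60 and Il6 by 0.40 ± 0.12 (edgeR adjusted p = 0.00333). Csf3 rose 19.4-fold (61.26 ± 3.86 against 3.155 ± 0.841 CPM), Ccl5 rose 4.07-fold and Il1b rose by 0.90 ± 0.08 log2. In KO, as in WT, Csf3 (72.7-fold), Il1b (6.03-fold, 8809 against 1460 CPM) and Ccl5 (5.89-fold) rose, and Tnf fell by 0.35 log2. Il6 (3.77-fold), Cxcl2 (2.04-fold) and Cxcl1 (1.48-fold), which fell in WT, rose in KO, as did Il12b (2.66-fold). Il10 did not pass (-0.003 ± 0.09, edgeR adjusted p = 0.981). The largest rises in WT were of the channel-like gene Tmc3 (65.4-fold, from 0.172 CPM), the interleukin 19 gene Il19 (78.08 ± 3.93 against 1.706 ± 0.569 CPM, 45-fold) and Csf3. The largest falls were of the OX40 ligand gene Tnfsf4 (42.8-fold), the cytokine signalling inhibitor gene Cish (38.3-fold) and the urokinase gene Plau (12.61 ± 1.23 against 292.5 ± 30.7 CPM, 23.1-fold). In WT 7974 genes differed (3753 higher and 4221 lower at 7 h), and in KO 8304 (3946 higher and 4358 lower).

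In WT, macrophage effector genes rose from 3 h to 7 h in 19 of 24 members and fell in 2 (camera adjusted p = 4.76e-17), with the prostaglandin synthase gene Ptges at 6.93-fold and the lipocalin gene Lcn2 at 5.2-fold. Glycolysis and hypoxia genes rose in 19 of 20 and fell in 0 (3.82e-14), with the lactate transporter gene Slc16a3 at 4.58-fold. Cholesterol synthesis genes rose in 17 and fell in 1 of 20 (9.98e-10), with the lanosterol synthase gene Lss at 3.63-fold. Proliferation genes fell in 21 of 22 and rose in 0 (1.66e-11). NF-kB pathway and feedback genes fell in 18 of 24 and rose in 2 (8.49e-09), with the adhesion molecule gene Icam1 at -1.99. Cytokines and chemokines fell in 18 and rose in 7 of 31 (0.0125, adjusted p = 0.512 with an estimated correlation). AU-rich element transcripts fell in 14 and rose in 4 of 22 (0.0257, adjusted p = 0.331 with an estimated correlation). Type I interferon genes did not pass as a list (18 higher and 13 lower of 33, camera adjusted p = 0.97, tested as down with a median of 0.30). Within it, Cxcl10 was 14.5-fold lower at 7 h. For each of the 7 lists that passed, the counts adjusted over the list alone were the same.

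In KO, cytokines and chemokines went up from 3 h to 7 h in 16 and down in 10 of 31 members (camera adjusted p = 0.0348, adjusted p = 0.687 with an estimated correlation, 0.0503 without the length trend). Regnase-1 targets went up in 10 and down in 3 of 14 (3.85e-08). Effector genes (22 up and 1 down of 24; 9.24e-30), glycolysis and hypoxia (20 up and 0 down of 20; 1.81e-18) and cholesterol synthesis (16 up and 1 down of 20; 2.66e-06) rose in KO too. Osteoclast markers fell in 6 of 8 and rose in 1 (0.0215). The list call for cytokines and 3 others depended on the preset correlation. The others were proliferation (17 down and 1 up of 22; 9.11e-07, adjusted p = 0.0705 with an estimated correlation) and NF-kB pathway and feedback (14 down and 3 up of 24, 15 and 3 adjusted over the list alone; 0.0304, adjusted p = 0.668 with an estimated correlation), and lastly AU-rich element transcripts (11 up and 8 down of 22, 11 and 9 adjusted over the list alone; 0.0207, adjusted p = 0.323 with an estimated correlation). Lcn2 rose 9.16-fold and the arginine transporter gene Slc7a2 7.46-fold in KO.

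The genotype difference in the change from 3 h to 7 h passed for 1690 genes. Of these 749 were more positive and 941 more negative in KO (265 and 1498 with stable-reference scaling). Among cytokines it was 2.31 ± 0.16 log2 for Il6, 1.91 ± 0.19 for Csf3, 1.69 ± 0.12 for Il1b, 1.64 ± 0.13 for Il10 and 1.63 ± 0.13 for Cxcl2. It was 1.59 ± 0.20 for Il12b, 1.44 ± 0.15 for Cxcl1, 0.53 ± 0.18 for Ccl5 (edgeR adjusted p = 0.0459) and 0.29 ± 0.08 for Tnf (edgeR adjusted p = 0.00879). The largest positive differences were in F3, encoding tissue factor (3.33 ± 0.26), the axon guidance gene Draxin (3.14 ± 0.54, from 0.0699 CPM in KO at 3 h), and Trem1 (3.02 ± 0.15), then D16Ertd472e (2.50 ± 0.15), the deubiquitinase gene Stambpl1 (2.49 ± 0.16) and Ddit4 (2.44 ± 0.16). The largest negative ones were in Rab3il1 (-2.51 ± 0.12), Hip1 (-2.45), the Ras exchange factor gene Rasgef1b (-2.14), the prostaglandin E receptor gene Ptger4 (-1.97), the actin regulator gene Mtss1 (-1.97) and the cyclin-dependent kinase gene Cdk20 (-1.95). N4bp1 differed by 0.38 ± 0.11 (edgeR adjusted p = 0.0113).

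By list, the difference between genotypes in the 3 h to 7 h change was positive for Regnase-1 targets (11 of 14 higher and 0 lower, 12 and 0 adjusted over the list alone; median 1.52; camera adjusted p = 8.63e-37) and cytokines and chemokines (17 of 31 and 0, 19 and 0 adjusted over the list alone; 6.76e-35). It was also positive for AU-rich element transcripts (16 of 22 and 2, 17 and 2 adjusted over the list alone; 8.49e-35) and macrophage effector genes (11 of 24 and 2, 14 and 2 adjusted over the list alone; 6.4e-17), as well as NF-kB pathway and feedback (15 of 24 and 0, 17 and 0 adjusted over the list alone; 5.32e-12) and immediate early genes (9 of 25 and 2, 11 and 3 adjusted over the list alone; 1.03e-05). It was negative for macrophage markers (0 higher and 7 lower of 16, the same adjusted over the list alone; 0.000127). With the preset correlation alone, glycolysis and hypoxia (6 and 0 of 20, 11 and 0 adjusted over the list alone; 5.25e-05, adjusted p = 0.108 with an estimated correlation) and the Toll-like receptor pathway (3 and 7 of 29, 4 and 9 adjusted over the list alone; 0.0161, adjusted p = 0.42 with an estimated correlation) passed. So did the ribosomal list (0 and 0 of 44; 0.0161, adjusted p = 0.588 with an estimated correlation) and dendritic cell markers (4 and 0 of 12, 4 and 1 adjusted over the list alone; 0.0326, adjusted p = 0.191 with an estimated correlation).

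Under ActD, the transcript of N4bp1 went down in WT, and no change passed in KO (n = 3 libraries per time and genotype). In WT it was at 149 ± 13.5, 131.2 ± 4.2, 80.24 ± 7.85 and 57.63 ± 5.11 CPM after 0.5, 1, 2 and 4 h of ActD. In KO it was at 88.85 ± 0.539, 85.66 ± 3.94, 84.89 ± 3.08 and 87.74 ± 9.52 CPM. The log2 fold change of KO over WT was -0.75 ± 0.08 and -0.62 ± 0.08 after 0.5 and 1 h and did not pass after 2 h (0.08 ± 0.08, edgeR adjusted p = 0.451). After 4 h it was 0.61 ± 0.08 (edgeR adjusted p = 8.87e-08), when the libraries labelled KO held 1.52-fold more N4bp1 transcript than those labelled WT. Its slope was -0.34 ± 0.03 log2 per h in WT (edgeR adjusted p = 1.12e-12) and 0.01 ± 0.03 in KO (edgeR adjusted p = 0.692), a difference of 0.35 ± 0.04 (edgeR adjusted p = 1.04e-06). With stable-reference scaling the KO slope was -0.125 and the difference 0.40. Over 0 to 2 h alone the difference of 0.40 did not pass (edgeR adjusted p = 0.249).

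**Figure D2:**
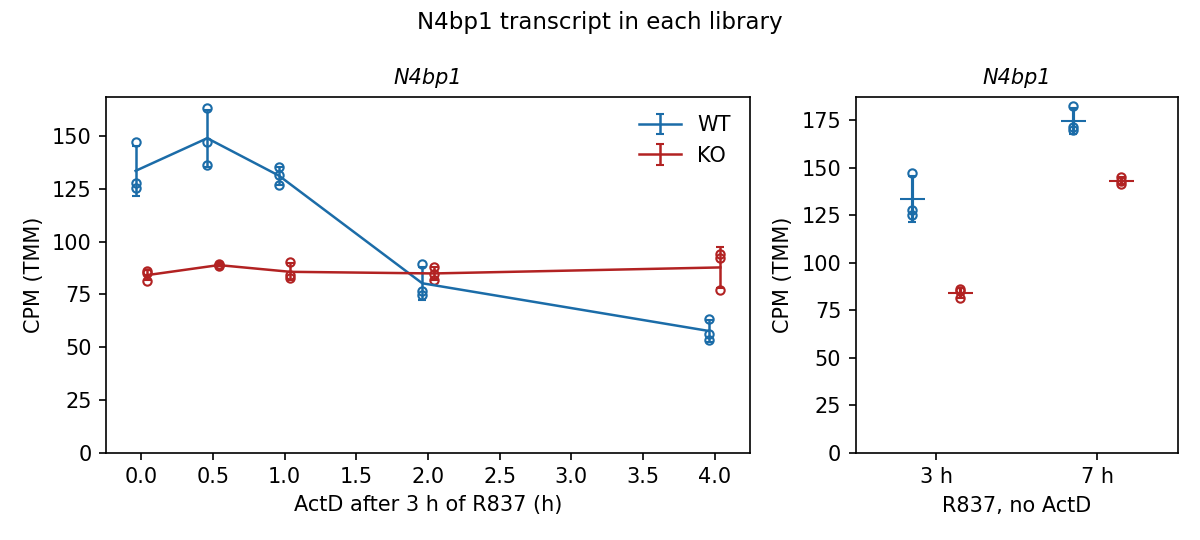
N4bp1 transcript in CPM (vertical axis) in each library (points, n = 3 per group, with means and bars of ± SD) over hours of ActD after 3 h of R837 and at 3 h and 7 h of R837, for WT and KO. WT went from 133.5 CPM at 3 h of R837 to 57.63 CPM after 4 h of ActD, while KO was at 84.09 and 87.74 CPM.

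The KO excess of cytokine transcripts persisted under ActD. Tnf was at 108.4 against 60.39 CPM after 0.5 h and 44.33 ± 2.61 against 22.43 ± 2.18 CPM after 4 h (log2 0.84 and 0.98). Il6 was at 1.63, 1.87, 1.51 and 1.73 log2 over WT after 0.5, 1, 2 and 4 h. Cxcl1 (1.45, 1.61, 1.25 and 1.63), Cxcl2 (1.05, 1.33, 1.02 and 1.18), Il1b (0.56, 0.70, 0.52 and 0.48), Il12b (0.84, 0.65, 0.60 and 0.65) and Csf3 (0.69, 0.95, 0.68 and 0.98) were higher in KO at each time. Ccl5 passed at 0.5 h (0.69), 2 h (0.40) and 4 h (0.33) and not at 1 h (0.27, edgeR adjusted p = 0.162). Il10 passed at none of the 4 times (edgeR adjusted p = 0.0751, 0.317, 0.439 and 0.942). Igha remained the highest by fold among the genes ranked, at 5.25, 5.27, 6.76 and 7.86-fold. The lowest were Pbk after 0.5 h (-1.52), the nestin gene Nes after 1 h (-1.78 ± 0.16) and the TRAIL gene Tnfsf10 after 2 h (-1.78) and 4 h (18.36 against 56.27 CPM, -1.61 ± 0.15).

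Genes differing between KO and WT numbered 3626 after 0.5 h of ActD (1883 higher and 1743 lower) and 2396 after 1 h (1032 and 1364). They numbered 4146 after 2 h (2023 and 2123) and 4896 after 4 h (2439 and 2457). Stable-reference scaling moved these splits to 2222 and 626, 440 and 2126, 2592 and 802, and 4923 and 618 through median shifts of 0.13, -0.13, 0.14 and 0.28 log2. Fitted on its 6 libraries alone, the contrast at 0.5 h called 2047 genes. Correlations of the difference with gene length were 0.22, -0.29, 0.14 and 0.24, and 83.1, 79.1, 89.8 and 78.6% of the calls remained without that trend.

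Regnase-1 targets were higher in KO in 13, 11, 11 and 12 of 14 members and lower in 0 after 0.5, 1, 2 and 4 h of ActD, the same adjusted over the list alone (camera adjusted p = 6.37e-23, 1.33e-26, 1e-16 and 7e-18). After 4 h, NF-kB pathway and feedback genes were higher in 20 of 24 and lower in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 8.01e-24). AU-rich element transcripts were higher in 16 of 22 and lower in 0 (18 and 0 adjusted over the list alone; 2.23e-16). Cytokines and chemokines were higher in 19 of 31 and lower in 5 (20 and 6 adjusted over the list alone; 6.11e-13). Also after 4 h, proliferation genes were lower in 18 of 22 and higher in 0 (18 and 1 adjusted over the list alone; 1.79e-12). Dendritic cell markers were higher in 5 of 12 and lower in 0 (the same adjusted over the list alone; 1.39e-07), with the invariant chain gene Cd74 at 1.32. IKK family and caspase-8 complex genes were higher in 11 of 24 and lower in 2 after 4 h (the same adjusted over the list alone; 0.00427), with Birc2 at 0.99. They did not pass after 1 h or 2 h (0.174 and 0.232). Type I interferon genes were lower in 17 of 33 and higher in 5 after 4 h (19 and 5 adjusted over the list alone; 0.000757, adjusted p = 0.407 with an estimated correlation). The antiviral gene Rsad2 was at -1.04 and Cxcl10 at 1686 against 2842 CPM.

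Also after 4 h of ActD, macrophage effector genes were higher in KO in 16 of 24 and lower in 4 (17 and 4 adjusted over the list alone; camera adjusted p = 3.02e-09). Cholesterol synthesis genes were lower in 15 of 20 and higher in 1 (16 and 1 adjusted over the list alone; 9.01e-07). Fibroblast and stromal markers were higher in 8 of 11 and lower in 0 (the same adjusted over the list alone; 6.36e-07). With the preset correlation alone, mRNA decay factors (16 of 32 higher and 4 lower, 17 and 4 adjusted over the list alone; 0.00219, adjusted p = 0.296 with an estimated correlation) and immediate early genes (10 of 25 and 1, 11 and 1 adjusted over the list alone; 0.0138, adjusted p = 0.187 with an estimated correlation) passed as up. B cell markers also passed as up (3 of 8 and 0, the same adjusted over the list alone; 0.0453, adjusted p = 0.19 with an estimated correlation), and the ribosomal list as down (1 of 44 and 19, the same adjusted over the list alone; 0.000757, adjusted p = 0.356 with an estimated correlation). Without the length trend the calls of the decay factor (0.063) and ribosomal (0.156) lists ended.

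Relative decay under ActD had the same direction in the genotypes for nearly all genes whose slopes passed in both. Among these, slopes were negative in both for 4352 genes, positive in both for 3976 and opposite for 5. Directions of the other genes were not counted. Dusp2, encoding a nuclear MAP kinase phosphatase, had the lowest slope in WT (-4.18 ± 0.41 log2 per h, -3.23 in KO). The cytokine signalling inhibitor gene Socs1 was at -2.88 ± 0.25 in WT and -3.24 in KO. A straight line did not describe these falls, which slowed with time: in WT, Dusp2 was 63.2-fold lower at 1 h and 580-fold at 4 h, and Socs1 22.4-fold and 129-fold. Tnf had slopes of -1.18 ± 0.25 and -1.16 ± 0.24, but most of its fall came within 0.5 h (15-fold in WT and 16-fold in KO, against 38-fold and 38.6-fold at 4 h), so its slope is not its rate of decay. Among transcripts that went up relative to the average were Saa3, encoding an acute-phase protein (0.75 ± 0.05 in WT, 0.55 in KO) and Il12b (0.38 and 0.40), as well as Ccl5 (0.50 and 0.44) and Il1b (0.11 ± 0.04 and 0.10 ± 0.04, edgeR adjusted p = 0.0126 and 0.0189). With stable-reference scaling the Il1b slopes were -0.086 and -0.035. Il6 (-0.17 ± 0.15 and -0.10 ± 0.13, edgeR adjusted p = 0.295 and 0.519) and Il10 (-0.20 and -0.15, edgeR adjusted p = 0.187 and 0.318) did not pass in either genotype.

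**Figure D3:**
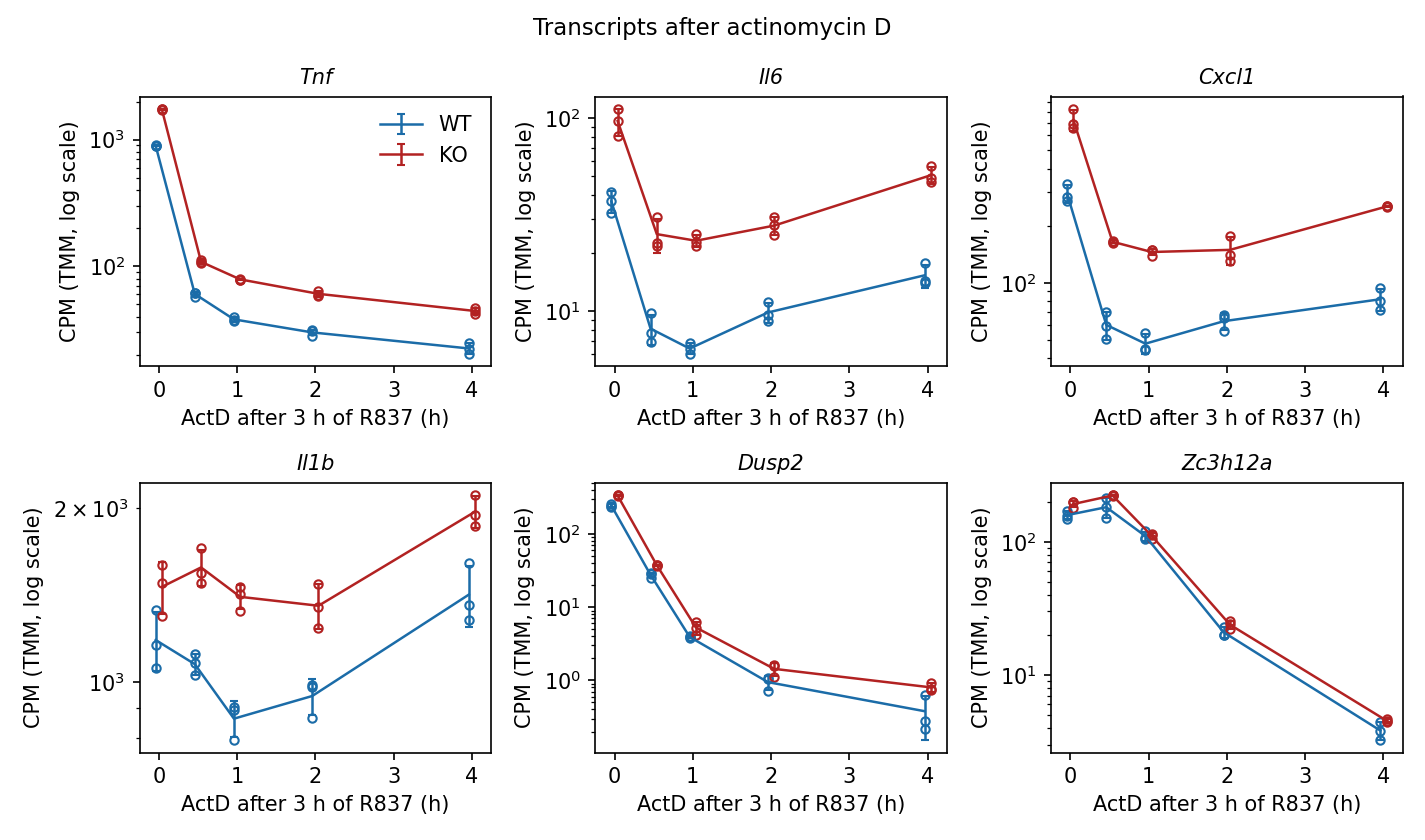
Transcript level in CPM (vertical axis, log scale) over hours of ActD after 3 h of R837 for Tnf, Il6, Cxcl1, Il1b, Dusp2 and Zc3h12a in WT and KO (points are libraries, lines are means, bars are ± SD, n = 3). Dusp2 was 580-fold lower in WT after 4 h than before ActD and Tnf 38-fold, whereas Il6 was lower by 2.57 log2 at 1 h and by 1.21 log2 at 4 h.

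Slopes passed for 9514 genes in WT (4803 positive and 4711 negative) and 9220 in KO (4379 and 4841). With stable-reference scaling they were 683 and 9094 in WT and 705 and 7900 in KO, through shifts of the median slope by -0.19 and -0.14 log2 per h. Slopes fell with gene length (Spearman correlation -0.38 in WT and -0.36 in KO). The difference in slope passed for 9 genes, 7 positive and 2 negative (edgeR quasi-likelihood; 1141 at unadjusted p < 0.05; 16 by DESeq2), and for 3 to 10 when 1 library was left out. After N4bp1 they included the inhibitory receptor gene Btla (0.35 ± 0.07), the splicing factor gene Srsf4 (0.18 ± 0.04, edgeR adjusted p = 0.0498) and the autophagy receptor gene Sqstm1 (0.14 ± 0.02). Also among them were Rcsd1, encoding an actin capping regulator (0.13 ± 0.02), the class II gene H2-Aa (0.12 ± 0.02), Fcgr1 (-0.14 ± 0.03) and the heme oxygenase gene Hmox2 (-0.11 ± 0.02). For Tnf (0.02 ± 0.29, edgeR adjusted p = 0.994) and Il6 (0.07 ± 0.19, edgeR adjusted p = 0.961) no difference in slope was found. The SE of these fits also held the misfit of the line. For both genes they were too wide to exclude a KO slope higher by 0.35 log2 per h. Compared without a line, the KO excess of Tnf given above was nearly the same before ActD and after 4 h. That of Il6 was 1.38 and 1.73 log2.

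By list, immediate early genes had negative slopes in 24 of 25 in WT and 23 in KO and positive in 0 (camera adjusted p = 9.18e-06 and 2.26e-05, adjusted p = 0.451 and 0.393 with an estimated correlation). Slopes of mRNA decay factors were negative in 25 of 32 in each genotype (2.74e-05 and 7.18e-05), and those of NF-kB pathway and feedback genes in 19 and 17 of 24 (6.91e-06 and 0.000367). Both lists had adjusted p = 0.317 in WT and 0.383 in KO with an estimated correlation. Type I interferon genes were positive in 27 and 26 of 33 (2.4e-07 and 2.26e-05, adjusted p = 0.317 and 0.383 with an estimated correlation) and the ribosomal list in 41 and 42 of 44 (1.43e-06 and 1.18e-05, adjusted p = 0.423 and 0.383 with an estimated correlation). The Toll-like receptor pathway (negative in 17 and 18 of 29, 0.00177 and 0.000817, adjusted p = 0.423 and 0.383 with an estimated correlation) and p53 targets (negative in 12 and 11 of 17, 0.0322 and 0.0413, adjusted p = 0.453 and 0.384 with an estimated correlation) passed as down. Macrophage effector genes passed as up (positive in 15 of 24 in each genotype, 15 and 16 adjusted over the list alone, 0.0036 and 0.00256, adjusted p = 0.182 and 0.157 with an estimated correlation), as did macrophage markers in WT (12 of 16, 0.0275, adjusted p = 0.317 with an estimated correlation). Without the length trend the p53 call in KO ended (0.0614). In the difference between slopes, dendritic cell markers were positive in 2 of 12 and negative in 0 (5 and 0 adjusted over the list alone; camera adjusted p = 7.52e-09). NF-kB genes (1 and 0 of 24, 2 and 0 adjusted over the list alone; 1.3e-06, adjusted p = 0.16 with an estimated correlation) and interferon genes (0 and 0 of 33, 0 and 2 adjusted over the list alone; 2.7e-07, adjusted p = 0.236 with an estimated correlation) passed only with the preset correlation. So did fibroblast and stromal markers (up, 0 and 0 of 11, 0.000478, adjusted p = 0.206 with an estimated correlation), inflammasome and cell death (down, 0 and 0 of 24, 0 and 3 adjusted over the list alone; 0.0014, adjusted p = 0.0627 with an estimated correlation) and B cell markers (up, 0 and 0 of 8, 2 and 0 adjusted over the list alone; 0.00188, adjusted p = 0.0627 with an estimated correlation). Immediate early genes and AU-rich element transcripts also passed as up with 0 members called (0.0408 each, adjusted p = 0.73 with an estimated correlation), and not without the length trend (0.195 and 0.0969). Regnase-1 targets did not pass (0 and 0 of 14; 0.157).

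Compared at the same 7 h after R837, macrophages in which transcription went on held more of many short-lived transcripts than those given ActD for the last 4 h (n = 3 libraries per group). In WT, Dusp2 was at 129.8 ± 1.02 CPM without and 0.3791 ± 0.228 CPM with ActD (325-fold). Tnf was 25.5-fold, Csf3 24-fold and the NF-kB inhibitor gene Nfkbia 75.8-fold higher without ActD. Il6 (0.88 ± 0.13 log2), Cxcl1 (0.98), Il1b (0.64) and Ccl5 (0.30) were higher and Cxcl2 did not pass (0.16 ± 0.09, edgeR adjusted p = 0.104). Il10 (-0.30 ± 0.10) and Il12b (-1.41 ± 0.14, 2.66-fold) were lower without ActD, though Il10 was at 0.406 with stable-reference scaling. The chemokine genes Cxcl11 (-4.30 ± 0.17) and Cxcl10 (158.8 against 2842 CPM, -4.16 ± 0.08) and Plau (-4.17) were the lowest of those named. In KO, Tnf was 30.5-fold, Csf3 67.1-fold, Il6 7.17-fold, Il1b 4.47-fold, Cxcl1 4.24-fold and Il10 2.16-fold higher without ActD. Il12b did not pass (-0.14 ± 0.14, edgeR adjusted p = 0.35), and its value was positive with stable-reference scaling.

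In WT 10348 genes differed in this comparison (5216 higher and 5132 lower without ActD) and in KO 10187 (5224 and 4963). With stable-reference scaling they were 8553 and 1469 in WT and 7178 and 2417 in KO (median shifts of 0.72 and 0.44 log2). Immediate early genes were higher without ActD in 24 of 25 and lower in 0 in each genotype (camera adjusted p = 1.38e-21 in WT and 2.16e-27 in KO). AU-rich element transcripts were higher in 17 and lower in 3 of 22 in WT (3.13e-16) and higher in 21 and lower in 1 in KO (7.08e-27). Regnase-1 targets were higher in 10 and lower in 2 of 14 in WT (3.01e-05) and higher in 12 and lower in 0 in KO (6.01e-13). Each of these 3 lists had the same counts adjusted over the list alone. Macrophage effector genes were higher in 19 and lower in 5 of 24 in WT (0.00612, adjusted p = 0.136 with an estimated correlation) and higher in 20 and lower in 3 in KO (3.87e-07). The ribosomal list was lower in 41 of 44 in WT (4.68e-05, adjusted p = 0.304 with an estimated correlation) and in 36 in KO (37 adjusted over the list alone, 0.00202, adjusted p = 0.407 with an estimated correlation). Interferon genes were lower in 23 of 33 in WT (0.000257, adjusted p = 0.481 with an estimated correlation) and in 20 in KO (21 adjusted over the list alone, 0.00451, adjusted p = 0.57 with an estimated correlation). Of the other lists that passed with the preset correlation, none passed with an estimated correlation (lowest adjusted p = 0.0512 for p53 targets in WT). Cytokines and chemokines did not pass in WT (11 higher and 13 lower of 31, camera adjusted p = 1, tested as down with a median of -0.15 and a mean of 0.10). They passed in KO with the preset correlation (17 and 7; 0.00451, adjusted p = 0.387 with an estimated correlation). In WT, neutrophil, dendritic cell and T and NK cell markers were tested as down with positive medians (0.44, 0.54 and 1.93) and did not pass.

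The genotype difference in this comparison passed for 2013 genes, 922 of them positive and 1091 negative (219 and 2598 with stable-reference scaling). It was 1.96 ± 0.17 log2 for Il6, 1.52 ± 0.12 for Il1b, 1.49 ± 0.21 for Csf3, 1.41 ± 0.14 for Il10 and 1.27 ± 0.19 for Il12b. It was 1.15 ± 0.13 for Cxcl2, 1.11 ± 0.15 for Cxcl1, 0.62 ± 0.18 for Ccl5, 0.26 ± 0.09 for Tnf (edgeR adjusted p = 0.0338, -0.008 with stable-reference scaling) and -0.89 ± 0.11 for N4bp1. The largest were in Ddit4 (3.57 ± 0.50), F3 (3.21 ± 0.39), Trem1 (2.87 ± 0.17), Socs1 (2.81 ± 0.86, edgeR adjusted p = 0.0215), Nr4a1 (2.65 ± 0.40) and Stambpl1 (2.44 ± 0.20). Negative ones were in Ptger4 (-2.77 ± 0.36), Rab3il1 (-2.58 ± 0.12), the transporter gene Slco4a1 (-2.58 ± 0.29), Rasgef1b (-2.37 ± 0.16), Mtss1 (-2.26 ± 0.16) and Hip1 (-2.24 ± 0.19). By list it was positive for cytokines and chemokines (18 of 31 higher and 1 lower, 19 and 1 adjusted over the list alone; camera adjusted p = 3.57e-24) and Regnase-1 targets (9 of 14 and 0, 10 and 0 adjusted over the list alone; 1.07e-22). Also positive were macrophage effector genes (14 of 24 and 2, 16 and 3 adjusted over the list alone; 3.81e-18) and AU-rich element transcripts (12 of 22 and 3, 14 and 3 adjusted over the list alone; 1.7e-15). NF-kB pathway and feedback genes passed with the preset correlation alone (7 of 24 and 2, 7 and 3 adjusted over the list alone; 0.0152, adjusted p = 0.497 with an estimated correlation).

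Other lists passed camera in this genotype difference with the preset correlation alone. Positive were glycolysis and hypoxia (6 of 20 higher and 0 lower, 8 and 0 adjusted over the list alone; camera adjusted p = 0.000269, adjusted p = 0.199 with an estimated correlation) and proliferation (7 of 22 and 0, 8 and 0 adjusted over the list alone; 0.00209, adjusted p = 0.274 with an estimated correlation). So were the ribosomal list (8 of 44 and 0, 10 and 0 adjusted over the list alone; 0.00308, adjusted p = 0.498 with an estimated correlation) and type I interferon genes (6 of 33 and 4, 9 and 5 adjusted over the list alone; 0.0126, adjusted p = 0.601 with an estimated correlation). Negative were the Toll-like receptor pathway (3 of 29 and 9, 3 and 10 adjusted over the list alone; 0.0126, adjusted p = 0.452 with an estimated correlation) and macrophage markers (0 of 16 and 4, 0 and 5 adjusted over the list alone; 0.0139, adjusted p = 0.167 with an estimated correlation). B cell markers were negative too (0 of 8 and 3, the same adjusted over the list alone; 0.0492, adjusted p = 0.27 with an estimated correlation). Without the length trend the ribosomal and B cell calls ended (0.0672 and 0.0629).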

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

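The tests of exchanged labels, of slower decay, of Regnase-1 target scaling and of resumed transcription were chosen only after the result was seen. The results given first are those in which the genotypes differed in a change over time.

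From 3 h to 7 h of R837 the genotypes differed in 1690 genes. Log2 differences (KO change minus WT change) were 2.31 for Il6, 1.91 for Csf3, 1.69 for Il1b, 1.64 for Il10, 1.63 for Cxcl2, 1.59 for Il12b, 1.44 for Cxcl1, 0.53 for Ccl5, 0.29 for Tnf and 0.38 for N4bp1. The largest were 3.33 for F3, 3.14 for Draxin, 3.02 for Trem1, 2.5 for D16Ertd472e, 2.49 for Stambpl1 and 2.44 for Ddit4, and -2.51 for Rab3il1, -2.45 for Hip1, -2.14 for Rasgef1b, -1.97 for Ptger4 and for Mtss1 and -1.95 for Cdk20.

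Between 7 h of R837 and 3 h of R837 with 4 h of ActD the genotypes differed in 2013 genes, by 1.96 for Il6, 1.52 for Il1b, 1.49 for Csf3, 1.41 for Il10, 1.27 for Il12b, 1.15 for Cxcl2, 1.11 for Cxcl1, 0.62 for Ccl5, 0.26 for Tnf and -0.89 for N4bp1. The largest were 3.57 for Ddit4, 3.21 for F3, 2.87 for Trem1, 2.81 for Socs1, 2.65 for Nr4a1 and 2.44 for Stambpl1, and -2.77 for Ptger4, -2.58 for Rab3il1 and for Slco4a1, -2.37 for Rasgef1b, -2.26 for Mtss1 and -2.24 for Hip1. In relative decay slope 9 genes differed, among them N4bp1 and Btla (0.35 log2 per h each), Srsf4 (0.18), Sqstm1 (0.14), Rcsd1 (0.13), H2-Aa (0.12), Fcgr1 (-0.14) and Hmox2 (-0.11).

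On the TMM scale, N4bp1 transcript fell under ActD in WT and not in KO, so that after 4 h the libraries labelled KO held more of it. An exchange of genotype labels at 4 h was excluded, since 99.1% of the genes at least 2-fold apart in the same direction at 3 h and 7 h (114 of 115) kept that direction. Slower decay of most transcripts in KO could not be decided, since slopes are relative to the average transcript and scaling removes a shared change. On that scale the median difference was 0.006 log2 per h over 2599 genes of similar slope. Of these, 18 had a difference at least that of N4bp1. Scaling was excluded for the difference in slope, which was 0.402 (stable reference) or 0.361 (RLE). It was not excluded for the flat course in KO, whose slope was negative with the stable reference. A KO transcript that decays more slowly than the WT transcript, relative to other transcripts, remains a hypothesis from the same data. The form of the KO transcript was not tested, and exon-level reads of the ActD course, not analysed here, would be needed to decide.

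The KO excess of Regnase-1 target transcripts was larger at 7 h than at 3 h, by a median of 1.515 log2. Scaling was excluded, since the median was 1.317 or more under RLE and stable-reference scaling. Slower decay of these transcripts in KO cannot be told apart from more transcription, although the median genotype difference in the change over 4 h of ActD was only 0.211 (upper quartile 0.32). At 1 h it was 0.305, which over 4 h would make 1.221, above the limit of 0.758 under which slower decay was to be excluded, but the ribosomal list differed by as much at 1 h (0.309, against -0.111 at 4 h) and over all genes the 1 h difference followed gene length (Spearman correlation -0.51), so the 1 h value decides nothing. What keeps it open is that Zc3h12a, which encodes Regnase-1, itself fell 39.8-fold in WT and 42-fold in KO by 4 h of ActD, and that decay between 3 h and 7 h of R837 was not measured.

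Cytokine transcripts (Il6, Cxcl1, Cxcl2, Il10, Il23a, Ccl3, with Tmcc2) fell within 1 h of ActD and were higher again at 4 h on the relative scale. A general return of transcription after 1 h was excluded, since immediate early genes changed by a median of -2.429 log2 from 1 h to 4 h in WT. Loss of total RNA, which raises stable transcripts on a relative scale, cannot be told apart: the median rise was 1.175 in WT and 1.185 in KO, against 99th percentiles of 1.153 and 0.987 over 5351 genes with at least 20 CPM, with 4 and 5 of the 7 genes above them. Of the 5 genes with at least 20 CPM (without Tmcc2 and Il23a), Cxcl2 and Il6 were above in WT, and these with Ccl3 and Il10 in KO. The ribosomal list, the stable reference, rose by a median of 0.747 in WT and 0.312 in KO over the same hours. Each of the 7 genes rose more than that (lowest Cxcl1, 0.879 and 0.851), but they had been picked by their rise. By a rule set before the result was seen, a median in WT above the 99th percentile would have excluded loss of total RNA, and it was above. Loss of total RNA is kept open by a criterion that was not in that rule. The median in WT was above its percentile by less than the spread of the genes (lower quartile 1.123). That median was also the value of Tmcc2, at a mean of only 1.329 CPM. No biological explanation was tested.

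Each contrast of 3 against 3 libraries called more genes than any of the 9 other splits of its 6 libraries, which called between 0 and 3 genes, so the real one was 1 of 10 and splits this few cannot give a share under 0.05. Of 50 splits of the labels, 2 called as many genes as the genotype difference in the 3 h to 7 h change, the real one included (up to 2989), and 2 as many as the difference in slope (up to 2986). For the slopes only the real order of times did so (1 of 50 in WT and in KO). For the genotype difference between 7 h of R837 and 4 h of ActD, 7 of 50 did so (up to 5867), so a count of 2013 did not stand out among them. In splits of genotype within conditions the genotype difference itself enters when the labels of one condition are exchanged. The ranks of the genotype differences in a change, a comparison or a slope therefore do not measure chance alone. No conclusion was drawn from them.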

How the results depend on the processing

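Removal of the gene length trend, the contrasts at single ActD times and the removal of 2 libraries together were chosen only after the result was seen. Of the named genes, 12432 values kept direction and side of the threshold over all alternatives, 292 became weaker, 45 stronger and 13 reversed, and of the gene lists 1263 kept both, 119 became weaker, 113 stronger and 5 reversed. Of the 12432, 6479 came from fits with 1 library left out, which share nearly all libraries with the main fit. DESeq2 left 718 named values the same, and RLE normalization 720. Stable-reference scaling left 670 the same, with 38 weaker, 8 stronger and 9 reversed. Slopes over 0 to 2 h left 108 the same, with 9 weaker, 8 stronger and 3 reversed. An estimated correlation ended 80 list calls. Differences below about 1.5-fold at 3 h, and slope differences below 0.35 log2 per h, were found only in part in simulated data. Only genes with a mean CPM of at least 5 were changed there. Of 9 genes looked at for near-identical copies, Gapdh and Rps6 had too few counts to test. No paired analysis was possible because the labels carry no replicate numbers.

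At adjusted p under 0.01 the count was 2173 at 3 h, 2188, 1375 and 2574 after 0.5, 1 and 2 h of ActD, 1066 and 1082 for the genotype differences in the 3 h to 7 h change and in 7 h of R837 against 4 h of ActD, and 3 for the slope difference, by the construction of the threshold. With only the libraries compared, 2047 genes were called after 0.5 h of ActD, where fewer libraries were fitted. The slope difference was called for 0 genes over 0 to 2 h, 16 with DESeq2, 6 with the stable reference and 6 without replicate 3 of WT at 0.5 h and at 4 h of ActD. The planned contrast of 4 h against 0 h called 11 (8 positive and 3 negative). At the other single times against 0 h it was called for 0 genes at 0.5 h (366 at unadjusted p < 0.05 by edgeR quasi-likelihood), 8.4e+02 at 1 h (171 positive and 666 negative), 2 at 2 h and 612 for all 4 times at once. Those at 1 h became 4 once the length trend was removed, which had a correlation of -0.51 with that difference. The cause of the length trend was not tested.

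Leaving out 1 library gave 2202 genes at 3 h without KO replicate 1 and 2375 without WT replicate 3 (up to 4268). The range was 3429 to 3625 at 7 h, 2433 to 4453, 1741 to 2000, 2990 to 3899 and 3341 to 4811 after 0.5, 1, 2 and 4 h of ActD, 7433 to 7539 and 7699 to 8014 for 7 h against 3 h in WT and KO, and 1289 to 1954 for their difference. It was 9927 to 10034 and 9749 to 9873 for 7 h of R837 against 4 h of ActD, 1374 to 2215 for their difference, 8842 to 9546 and 8750 to 9263 for the slopes and 3 to 10 for their difference. For the last, the count was 3 without replicate 1 of WT at 4 h, 5 without replicate 2 of WT at 4 h, 5 without replicate 1 or 3 of KO at 4 h, 4 without replicate 2 of KO or of WT at 0 h and 5 without replicate 1 of WT at 0 h. The cause was not tested.

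Values that reversed were as follows. For 7 h of R837 against 4 h of ActD in WT, Il10 was 0.406 with the stable reference and 0.05 without the length trend, and the ribosomal gene Rpl4 0.156 with the stable reference. By fry in WT, cytokines and chemokines (adjusted p = 0.0102), dendritic cell markers (0.0359) and mast cell markers (0.00998) were up, and in KO neutrophil (0.0465) and fibroblast markers (0.0106). In KO Il12b was 0.303 with the stable reference, and in the genotype difference Tnf was -0.008. Among slopes in WT with the stable reference, Il1b was -0.086, Rpl4 -0.053 and C1qb -0.01, and over 0 to 2 h Il1b was -0.174. Among slopes in KO, Il1b was -0.035 and N4bp1 -0.125 with the stable reference, and over 0 to 2 h Il1b was -0.086 and Csf3 -0.367. The stable reference reversed signs through its median shift, and for the rest the cause was not tested.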

Other observations

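The counts over all 6 conditions, the comparison of neighbouring genes, the count of genes that fell and rose under ActD and the genes named, N4bp1 and the list tests apart, were chosen only after the result was seen.

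In all 6 conditions, 411 genes were higher and 260 lower in KO than in WT, with 52 and 6 at least 2-fold in each. The 6 conditions may share mice, so they may not be independent repeats. Among the higher ones were 5 immunoglobulin genes given here, for which no enrichment was tested. Igha was at 27.58 ± 2.41 CPM in KO and 4.142 ± 0.484 CPM in WT at 3 h, Jchain at 17.13 ± 0.401 and 4.542 ± 0.273 CPM, and Iglc2, encoding a lambda light chain, at 1.995 ± 0.898 and 0.5389 ± 0.0282 CPM. The kappa variable gene Igkv3-4 was at 0.7798 ± 0.332 and 0.08036 ± 0.0398 CPM, and Igkv4-58 at 0.2475 ± 0.0359 and 0 CPM. B cell markers as a list did not pass at 3 h or 7 h (camera adjusted p = 0.673 and 0.948) or after 0.5, 1 and 2 h of ActD (0.317, 0.277 and 0.305). They passed as up after 4 h of ActD (3 of 8 higher and 0 lower, the same adjusted over the list alone, 0.0453, adjusted p = 0.19 with an estimated correlation), with Ighm at 0.72 and Cd79b at 0.49 log2. They also passed as up in the slope difference, with 0 of 8 called (2 and 0 adjusted over the list alone, 0.00188, adjusted p = 0.0627 with an estimated correlation).

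Other genes higher in KO in all 6 conditions were Ptx3, Ly6i (median log2 2.23), Rasgrp1 (2.02), Adora2a (1.96), Cxcl3 (1.90) and Inhba (1.85). The 6 genes at least 2-fold lower in each included the scavenger receptor gene Cd163 (0.2826 ± 0.0729 against 0.9004 ± 0.0692 CPM at 3 h), Ndnf, encoding a secreted neuron-derived factor (0.874 ± 0.156 against 3.757 ± 0.705 CPM), Nptx1 (median log2 -1.43) and the G protein gene Gna15 (-1.34).

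Genes within 5 Mb of N4bp1 differed between KO and WT in 28 of 84 at 3 h (33.3% against 27.7% elsewhere, Fisher exact p = 0.271) and in 24 of 84 at 7 h (28.6% against 30.6%, Fisher exact p = 0.812). Per library, N4bp1 ranged from 84.755 to 91.885 CPM in KO and from 134.678 to 158.457 CPM in WT at 3 h before TMM, and after 4 h of ActD from 68.928 to 84.26 in KO and from 43.836 to 56.039 in WT.

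Under ActD, 7 genes fell at least 2-fold by 1 h and rose at least 1.5-fold from 1 h to 4 h in both genotypes, 6 of them in the cytokine list. A Fisher exact test of that share was run but is void, because the pattern was first seen in cytokine transcripts and its limits were set afterwards. In WT the fall and the rise were -1.99 and 1.65 log2 for Il23a, -2.26 and 1.57 for Cxcl2, -2.57 and 1.37 for Il6, -1.08 and 1.18 for Tmcc2, -1.42 and 1.13 for Ccl3, -2.40 and 1.12 for Il10 and -2.66 and 0.88 for Cxcl1.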
